A study of Mus musculus with 6 samples.

How the data were processed

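Libraries were made with a stranded mRNA kit from total RNA of mouse peritoneal macrophages kept in serum-containing medium, per the labels, with 3 negative control and 3 Rfx1 overexpression libraries. The authors deposited 1 table of raw read counts per gene for the 6 libraries, 54532 Ensembl gene identifiers in all. The submitters' processing notes name featureCounts 1.5.0-p3, DESeq2 1.20.0 and the mouse genome build mm10. The aligner, the annotation release and the strand setting are not given in the sources used here. Reads from overlapping or antisense genes may therefore be shared, and genes with near-identical copies are uncertain, among them Gapdh, the Ly6, MHC and histone families and mitochondrial genes with nuclear copies.

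Identifiers were matched to GENCODE mouse release 21, on the same build, for symbols and coordinates. Of the identifiers, 54495 matched, 37 did not and 219 shared a symbol with another. Each library held 16461277 to 18795575 counts. Replicates were compared before averaging: correlations of log2 CPM were 0.931 to 0.978 within groups and 0.837 to 0.932 between groups, and every pair within a group differed by more than sampling noise, with a chi-square per degree of freedom of at least 41.8.

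Differences were tested with edgeR 4.0.16 in R 4.3.3 on the counts as deposited, with TMM scaling, edgeR's default filter on low counts by group, robust quasi-likelihood fits, group as the only term and Benjamini-Hochberg adjustment at 0.05. The filter kept 13454 genes and left out 41078. CPM values use TMM-scaled library sizes. Standard errors of log2 changes are the change divided by the square root of the F statistic. A group with 0 counts was set to a floor of 3 counts over the group and the fold is then a lower bound; with 1 to 3 counts the ratio has a 95% counting interval. Such intervals and floors cover counting error only, since reads without molecular identifiers are not independent molecules.

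Lists of genes (40, of which 38 had at least 5 tested members) for macrophage programmes, other cell types and RNA quality were tested with limma 3.58.1's camera on log2 CPM with a prior count of 2 and a preset inter-gene correlation of 0.01, adjusted over the lists. The correlation estimated from the data and the fry test were alternatives. The sample groups, designs, lists, alternatives and the rule for named genes were fixed before the data were examined. The rule named Rfx1; the 10 largest rises and 10 largest falls among genes that passed, did not overlap between groups, reached a group mean of 5 CPM and had no predicted or clone symbol; up to 2 risen and 2 fallen members of each list by smallest p; and a panel of 15 macrophage genes given whatever the test showed. Genes named outside it are said to be chosen after their values were seen.

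Tests were checked on simulated counts for 13454 genes with the real means and library sizes. In 1 simulated draw, of 50 genes changed by each size, 80% were recovered at a log2 change of 2, 54% at -2, 8% at 1 and 4% at -1, and 4 of 13254 unchanged genes were called. Changes of 1 log2 unit were thus mostly missed in that draw. Far fewer genes were changed in the draw than were called in the data, which makes the adjusted threshold stricter. These shares therefore do not carry over to the test on the real counts. Alternatives were RLE and upper-quartile factors, library size only, DESeq2 1.42.0, limma-voom with quality weights, other filters on low counts, the replicate number as a block, stricter thresholds and leaving out each library in turn. Leaving out control 1 with overexpression 3, and overexpression 1 with 2, were added after seeing the data.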

Results

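Messenger RNA was sequenced from cultured mouse peritoneal macrophages, the resident phagocytes of the abdominal cavity, in 3 negative control libraries and 3 libraries labelled as overexpressing Rfx1, a transcription factor of the regulatory factor X family. The comparison asks which transcripts differ when Rfx1 is overexpressed. Libraries held 16461277 to 18795575 counts assigned to genes, and 13454 genes had enough counts to be tested. Values are counts-per-million (CPM), given as mean ± SD with n = 3 libraries per group. Adjusted p-values are from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment unless another test is named. The labels do not say whether the libraries of a group came from separate animals or cultures, so p-values measure only the spread between these libraries. Every pair within a group differed by more than sampling noise, with a chi-square per degree of freedom of 41.8 to 205. These values argue against repeat sequencing of the same library as the source of that spread. Whether it lies between animals, cultures or the handling of the libraries was not tested.

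No difference in Rfx1 itself was detected between the groups, which does not exclude one, since its level varied widely between libraries of the same label. The gene (ENSMUSG00000031706, chromosome 8, positions 84066834 to 84096992 of mm10, + strand) had 57.6, 11.0 and 14.8 CPM in control libraries 1, 2 and 3 and 40.8, 36.4 and 23.2 CPM in overexpression libraries 1, 2 and 3. Group means were 27.8 ± 25.9 and 33.5 ± 9.16 CPM, a log2 difference of 0.27 ± 0.58 (SE, adjusted p = 0.80). Mean log2 CPM, with a prior count of 2, differed by 0.62, and a 2-sided exact permutation test of that difference gave p = 0.5. The smallest p that 3 against 3 libraries allow is 0.1. The library labelled control 1 held the most Rfx1 mRNA of all 6, which goes against its label, and every direction given here rests on the labels. Without it the log2 difference was 1.37 (edgeR adjusted p = 0.024), and without control 2 or control 3 it was -0.10 or -0.04. Gene counts do not tell the endogenous transcript from an introduced one, and an introduced copy that lacks the annotated untranslated regions gives fewer counts.

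**Figure D1:**
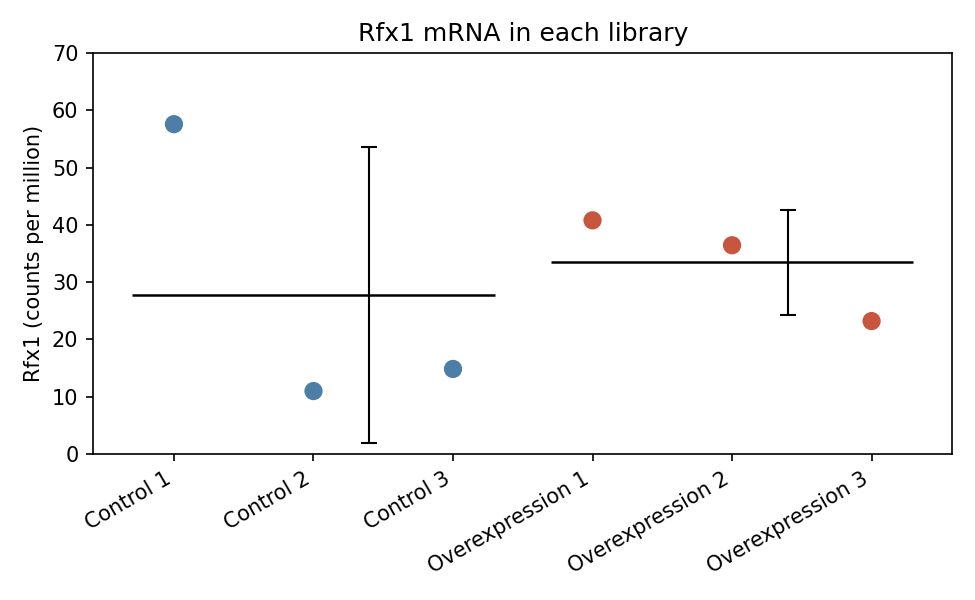
Rfx1 mRNA in CPM in each of the 6 libraries, controls in blue and overexpression libraries in red; horizontal lines are group means and the bars beside them 1 SD (n = 3). The library labelled control 1, at 57.6, lies above all 3 overexpression libraries.

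The libraries labelled as overexpressing Rfx1 differed widely from the controls in other genes. Nos2, which encodes inducible nitric oxide synthase, rose from 1.40 ± 1.76 to 2275 ± 1713 CPM (log2 change 10.63 ± 1.38 SE, adjusted p = 0.0026). Inhba, the activin A subunit, rose from 3.73 ± 0.491 to 945 ± 434 CPM (7.98 ± 0.44, adjusted p = 6.1e-05), and Lcn2, the iron-siderophore binding protein lipocalin 2, from 3.86 ± 1.28 to 955 ± 404 CPM (7.95 ± 0.51, adjusted p = 9.1e-05). Angptl7 fell from 32.0 ± 22.01 CPM to 0 counts, at least 508-fold lower against a floor of 3 counts over the group. In all, 928 genes were higher and 803 lower, 814 and 675 of them by at least 1 log2 unit. With library size as the only scaling, which moved the median log2 change of all genes to -0.20, 648 were higher and 910 lower.

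The other genes of largest rise were Bpifc (0 counts in the controls, at least 219-fold higher), Il17a, Il12a, Ly6i, Hsd11b1, Ccl5 and Cxcl3. Il17a, the cytokine interleukin 17A, was at 0.0157 ± 0.0273 CPM in the controls and 26.6 ± 15.9 CPM with overexpression, a ratio of 1545 with a 95% counting interval of 277 to 61060. Hsd11b1, which regenerates active glucocorticoid, rose from 0.113 ± 0.150 to 41.4 ± 13.7 CPM (adjusted p = 1.4e-04), and the chemokine gene Ccl5 from 7.71 ± 9.40 to 2207 ± 1557 CPM (adjusted p = 0.0041). Ly6i lies in a family of similar genes between which reads can be shared, and its call ended without overexpression 1 (adjusted p = 0.051). The other largest falls were Upk3b, Upk1b, Clca3a2, Fmod, Ogn, Cemip, Gpm6a, Lrrn4 and Cavin2. Upk1b lost its call without overexpression 1 or overexpression 3 (adjusted p = 0.062 and 0.073). Clca3a2 fell from 5.74 ± 0.610 CPM to 0 counts, at least 94.0-fold, and Cavin2 from 20.8 ± 14.1 to 0.0968 ± 0.0897 CPM (adjusted p = 0.0016).

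Libraries of the same label differed in how far they lay from the other group, and the cause was not tested. Overexpression 3 lay nearer the controls than the other overexpression libraries on the first principal component, at 23.2 against 89.5 and 74.1, with controls at -42.3, -66.2 and -78.2. Without it, 1657 genes were higher and 1800 lower. Leaving out control 2 left 454 and 280, control 3 528 and 388, overexpression 1 728 and 483, and overexpression 2 463 and 250. As an alternative chosen after seeing the data, leaving out both control 1 and overexpression 3 gave 1922 and 2022. These were the libraries of each label nearest the other group on that component. Setting overexpression 3 alone against the controls, with the spread taken from the controls, was another such alternative. Of the 1731 genes called with all libraries, none that was tested in these fits changed sign, though the fits share libraries with the one that called them.

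Many genes of inflammation rose. Of 20 tested inflammatory cytokines and mediators, 14 rose, 2 fell and 4 did not pass (16 and 2 adjusted over the list alone). Ptgs2, the inducible prostaglandin synthase, rose from 2.23 ± 0.443 to 136 ± 70.8 CPM (adjusted p = 1.4e-04), Il6 from 0.578 ± 0.312 to 22.8 ± 9.57 CPM (adjusted p = 3.1e-04) and Il1b from 0.795 ± 0.576 to 137 ± 110 CPM (adjusted p = 0.0053). Edn1, which encodes endothelin 1, fell from 3.43 ± 2.54 to 0.0456 ± 0.0790 CPM, a ratio of 81.0 with a 95% counting interval of 22.1 to 674 (adjusted p = 0.0097, and 0.058 without overexpression 2). The macrophage growth factor gene Csf1 fell by 1.41 on the log2 scale (adjusted p = 0.016), a call lost without control 2, control 3, overexpression 1 or overexpression 2 (adjusted p = 0.068, 0.063, 0.058 and 0.092). Of 20 chemokines, 8 rose and 2 fell (10 and 2 adjusted over the list alone). Cxcl3 rose from 0.484 ± 0.201 to 87.3 ± 49.7 CPM, while Cxcl13 fell by 5.28 and Cxcl5 fell by 2.86 on the log2 scale (adjusted p = 0.018 and 0.021). Neither fall passed without overexpression 1 (adjusted p = 0.080 and 0.11) or overexpression 2 (0.074 and 0.079), nor did Cxcl13 without control 2 (0.061) or Cxcl5 without overexpression 3 (0.087). Without control 1 the number of fallen chemokines was 4, and for overexpression 3 alone the median log2 difference of the list turned from 1.25 to -0.23. Of 24 NF-kB feedback genes, 15 rose and 1 fell (17 and 1 adjusted over the list alone), with the superoxide dismutase gene Sod2 up from 107 ± 6.94 to 932 ± 180 CPM (adjusted p = 2.0e-04). The fallen member, Dusp2, lost its call without control 1, control 2, control 3 or overexpression 2 (adjusted p = 0.064, 0.064, 0.10 and 0.12).

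In limma's camera test against all other genes, with a preset inter-gene correlation, these 3 lists were shifted upward with adjusted p = 2.2e-10, 3.2e-04 and 2.3e-09. With an estimated correlation the cytokine list had adjusted p = 0.34, the chemokines adjusted p = 0.38 and the NF-kB list adjusted p = 0.34. Tnf rose from 4.56 ± 1.34 to 17.5 ± 8.54 CPM (adjusted p = 0.011, and 0.064 without control 2), Ccl2 had 54.4 ± 38.1 and 73.7 ± 38.2 CPM (adjusted p = 0.70), and Il10 had too few counts to be tested. Of 26 Toll-like receptor genes, 7 rose and 3 fell (7 and 5 adjusted over the list alone), and the list's shift did not pass (camera adjusted p = 0.90). Leaving out control 1, control 2, control 3 or overexpression 2 left 5, 3, 4 or 4 risen, and library size as the only scaling left 4. Fallen members numbered 1 without control 1, control 2, overexpression 1 or overexpression 2, 5 without overexpression 3 and 7 with limma-voom. The lipopolysaccharide co-receptor gene Cd14 rose from 220 ± 42.9 to 3238 ± 1642 CPM and Tlr2 from 45.0 ± 19.2 to 270 ± 15.8 CPM. Tlr9, a receptor of unmethylated DNA, fell from 12.3 ± 3.52 to 1.66 ± 0.736 CPM, and Tlr4 had 75.1 ± 16.2 and 57.3 ± 13.4 CPM (adjusted p = 0.36).

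Interferon response genes and the MHC class I pathway moved upward with no tested member falling. Of 22 interferon gamma response genes 19 rose (22 adjusted over the list alone), of 41 type I interferon response genes 22 rose (35 adjusted over the list alone), and of 20 MHC class I presentation genes 14 rose (18 adjusted over the list alone). Cd274, which encodes the checkpoint ligand PD-L1, rose from 100 ± 26.0 to 1086 ± 354 CPM (adjusted p = 3.6e-04). Xaf1 rose from 7.46 ± 0.954 to 39.6 ± 10.0 CPM (adjusted p = 5.6e-04), and the proteasome activator gene Psme2 from 71.6 ± 16.5 to 363 ± 194 CPM (adjusted p = 0.0053). Camera gave adjusted p = 8.1e-13, 6.9e-17 and 6.6e-10 for the 3 lists, and with an estimated correlation adjusted p = 0.43, 0.35 and 0.43. The counts of risen genes depended on single libraries: leaving out control 2 left 8, 14 and 2, overexpression 1 left 9, 19 and 5, overexpression 2 left 13, 15 and 4, and control 3 left 18, 16 and 4. With limma-voom 21, 37 and 20 rose.

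MHC class II genes, whose transcription is known to involve a complex containing Rfx5, another member of the family, varied widely within each label. H2-Oa rose from 0.521 ± 0.204 to 9.84 ± 6.74 CPM (adjusted p = 0.0059), and the other 12 of 13 tested members did not pass (1 risen adjusted over the list alone). That count depended on the method and the libraries. With limma-voom 11 rose, without a filter on low counts 8, with the replicate number as a block 5 and with DESeq2 3. It was 4 without control 1 or without overexpression 3, and 10 without both, a pair chosen after seeing the data. Each of these lay nearest the other group on the first principal component, so the larger count without both is no support. H2-Ab1 had 599, 160 and 63.2 CPM in the controls and 2090, 1533 and 203 CPM with overexpression (log2 difference 2.22 ± 0.95 SE, adjusted p = 0.17, and 0.030 without control 1). Cd74 had 975 ± 1210 and 2853 ± 2380 CPM (adjusted p = 0.40). Both passed with limma-voom (adjusted p = 0.0030 and 0.013) and without a filter on low counts (edgeR adjusted p = 5.2e-10 and 1.6e-04). The groups overlapped in both genes, and the filtered fit of the same counts called neither. The unfiltered p-values thus do not measure the spread between these libraries. The list was shifted upward in the camera test (adjusted p = 0.017; adjusted p = 0.87 with an estimated correlation), a call lost without control 3, overexpression 1 or overexpression 2 (adjusted p = 0.16, 0.15 and 0.073). Setting overexpression 3 alone against the controls turned its median log2 difference from 1.34 to -0.42. None of 7 tested RFX family genes passed (0 adjusted over the list alone, camera adjusted p = 0.72). Without control 1 only Rfx1 itself did, and with limma-voom 1 member other than Rfx1. Of 44 cilium genes, a group RFX factors are known to control, 1 passed, Ift57, which rose (0 adjusted over the list alone, camera adjusted p = 0.33). Of the cilium genes, 10 rose with limma-voom, 5 without a filter on low counts and 3 with DESeq2. The count was 4 without control 1, 8 without overexpression 3 and 13 without both, the same pair chosen after seeing the data. Ift57 lost its call with library size as the only scaling (adjusted p = 0.083) and without control 2, control 3, overexpression 1 or overexpression 2 (adjusted p = 0.14, 0.13, 0.094 and 0.11).

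**Figure D2:**
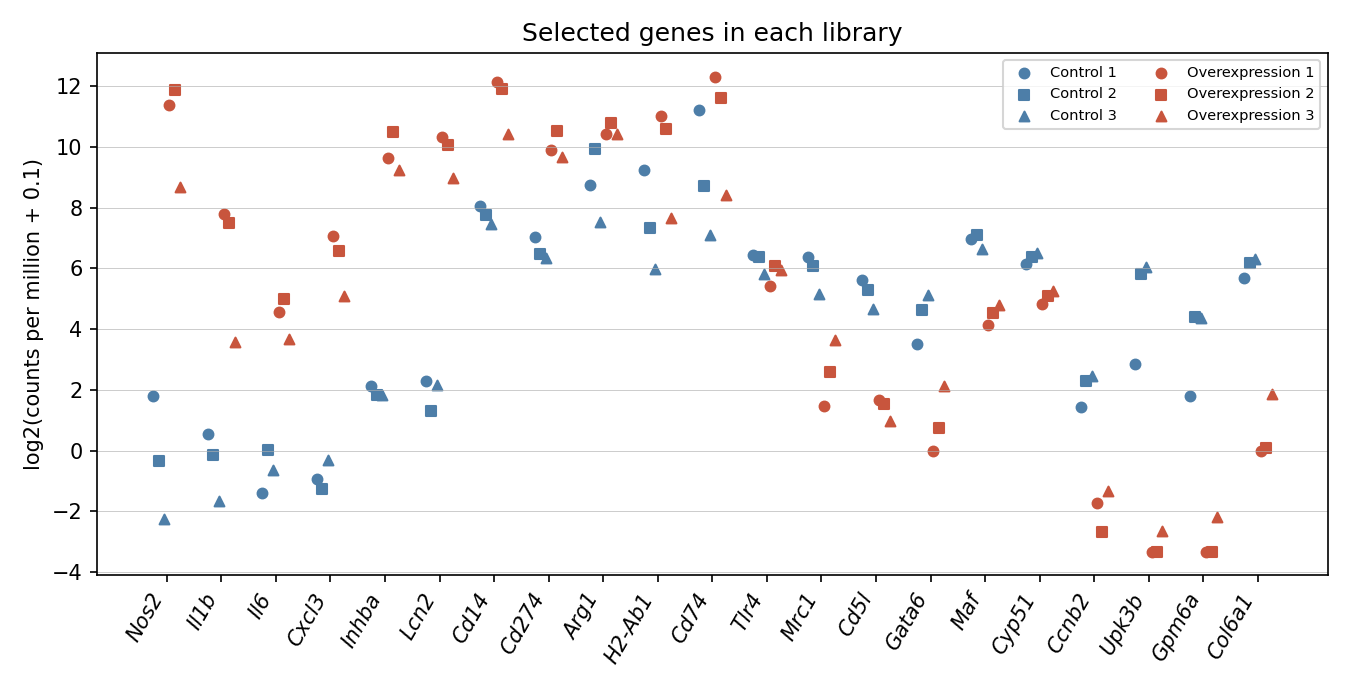
CPM of 21 genes in each library on a log2 axis, with 0.1 added before taking the logarithm; controls are blue, overexpression libraries red, and marker shapes give the library numbers. Nos2, Inhba and Lcn2 separate the groups completely, whereas H2-Ab1, Cd74 and Tlr4 overlap.

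Genes of glucose metabolism and sterol synthesis moved in opposite directions. Of 24 tested glycolysis and hypoxia genes 17 rose and none fell (21 and 0 adjusted over the list alone). The hexokinase gene Hk2 rose from 69.7 ± 11.1 to 303 ± 41.2 CPM (adjusted p = 5.8e-04) and Vegfa from 150 ± 24.0 to 640 ± 46.9 CPM (adjusted p = 7.7e-04). Of 29 sterol synthesis genes 14 fell and none rose (17 and 0 adjusted over the list alone), among them Cyp51, from 81.8 ± 10.3 to 33.4 ± 4.81 CPM (adjusted p = 0.0046), and Sc5d, from 136 ± 24.1 to 52.0 ± 11.1 CPM (adjusted p = 0.0057). Camera gave adjusted p = 6.9e-12 and 7.6e-07, and with an estimated correlation adjusted p = 0.34 and 0.28. Leaving out control 3 left 8 risen glycolysis genes and overexpression 2 left 10, and leaving out overexpression 2, control 2, control 3 or overexpression 1 left 4, 6, 7 or 9 fallen sterol genes.

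Of 48 tested cell cycle genes 16 fell, 2 rose and 30 did not pass (24 and 2 adjusted over the list alone), with the mitotic cyclin gene Ccnb2 down from 4.24 ± 1.45 to 0.186 ± 0.120 CPM (adjusted p = 0.0024) and Pclaf from 4.604 ± 0.803 to 0.592 ± 0.0727 CPM. The 2 that rose, Ccne1 and E2f1, act at entry into DNA synthesis, and both lost their calls with library size as the only scaling (adjusted p = 0.069 and 0.16). They also lost them when any 1 library was left out except overexpression 3 (adjusted p = 0.074 to 0.14 and 0.065 to 0.16), and E2f1 with upper-quartile scaling (adjusted p = 0.055) and without a filter on low counts (adjusted p = 0.069). Camera gave adjusted p = 3.9e-09 (adjusted p = 0.34 with an estimated correlation). Leaving out control 2, control 3 or overexpression 2 left 7, 7 or 8 fallen members, and limma-voom gave 26.

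Markers of macrophage identity changed in both directions. Of 23 tested large peritoneal macrophage genes 7 rose and 4 fell (7 and 4 adjusted over the list alone, camera adjusted p = 0.85). Risen members numbered 2 without control 2, 3 without overexpression 2, and 4 without control 3 or with library size as the only scaling. Gata6, the transcription factor that defines the large peritoneal subset, fell from 23.5 ± 11.7 to 2.26 ± 1.81 CPM (adjusted p = 0.0081) and Cd5l from 37.9 ± 12.0 to 2.58 ± 0.619 CPM (adjusted p = 2.0e-04), while Saa3 rose from 540 ± 117 to 9273 ± 4528 CPM (adjusted p = 5.2e-04). In control libraries 1, 2 and 3 Gata6 had 11.3, 24.7 and 34.6 CPM, lowest in control 1 like the mesothelial gene Upk3b (7.08, 56.9 and 66.3). Cd5l was highest there, with 49.3, 39.0 and 25.4 CPM. Whether the fall of Gata6 lies in macrophages or in mesothelial cells was not tested. Of 18 small peritoneal macrophage and monocyte genes 1 rose and 5 fell (1 and 5 adjusted over the list alone, camera adjusted p = 0.56), and 2 fell without control 2, overexpression 1 or overexpression 2. The risen member, Ly6c2, lost its call without control 2, control 3, overexpression 1 or overexpression 2 (adjusted p = 0.072, 0.055, 0.085 and 0.056), and 3 rose without overexpression 3 and 5 with limma-voom. Of 22 macrophage lineage genes 4 rose and 4 fell (5 and 6 adjusted over the list alone, camera adjusted p = 0.98), with the scavenger receptor gene Marco up from 3.76 ± 0.247 to 38.2 ± 10.6 CPM and Maf down from 121 ± 18.5 to 22.9 ± 5.20 CPM. In this list 2 rose and 1 fell without overexpression 2, 3 and 2 without control 2, 2 and 4 without control 3, 2 and 6 with library size as the only scaling, and 8 and 7 with limma-voom. Adgre1, which encodes F4/80, rose from 261 ± 96.9 to 674 ± 161 CPM (adjusted p = 0.024), a call lost with library size as the only scaling (adjusted p = 0.064) and without control 2, control 3 or overexpression 2 (adjusted p = 0.088, 0.085 and 0.086).

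Of 20 alternative activation genes 4 rose and 3 fell (6 and 3 adjusted over the list alone, camera adjusted p = 0.18). Risen members numbered 2 without overexpression 2 and 9 with limma-voom, and only 1 fell without control 1, control 2, overexpression 1 or overexpression 2. The mannose receptor gene Mrc1 fell from 62.5 ± 24.4 to 6.98 ± 4.92 CPM (adjusted p = 0.0064), Tgm2 rose from 149 ± 63.2 to 869 ± 65.4 CPM (adjusted p = 0.0015), and Arg1 had 530 ± 403 and 1514 ± 236 CPM (adjusted p = 0.083, 0.029 without control 2, 0.0085 with DESeq2, 0.0037 with limma-voom and 8.3e-05 without a filter on low counts). Of 26 cholesterol efflux and lipid handling genes 5 rose and 7 fell (6 and 8 adjusted over the list alone, camera adjusted p = 0.82). Fallen members numbered 3 without control 2 or overexpression 2 and 4 without control 3 or overexpression 1. Olr1, a receptor of oxidised lipoprotein, rose from 1.38 ± 0.282 to 36.0 ± 9.70 CPM, and the nuclear receptor genes Nr1h3 and Pparg fell, from 33.8 ± 1.79 to 12.1 ± 1.23 and from 31.8 ± 2.97 to 12.2 ± 1.67 CPM.

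Several markers of mesothelial cells, which line the peritoneum, fell in the libraries labelled as overexpressing Rfx1. Of 12 tested mesothelial genes 7 fell and none rose (11 and 1 adjusted over the list alone), and of 19 fibroblast and stromal genes 8 fell and none rose (9 and 0 adjusted over the list alone). Upk3b had 7.08, 56.9 and 66.3 CPM in control libraries 1, 2 and 3 and 0, 0 and 0.0590 CPM with overexpression (adjusted p = 0.0020, and 0.061 without overexpression 3), and Gpm6a 3.40, 21.2 and 20.6 against 0, 0 and 0.118 CPM. The collagen gene Col6a1 fell from 67.8 ± 14.6 to 1.80 ± 1.51 CPM (adjusted p = 4.9e-04). Camera gave adjusted p = 7.6e-07 and 2.3e-04, and with an estimated correlation adjusted p = 0.38 and 0.51. Leaving out overexpression 2 left 3 fallen stromal genes, control 2 4, and control 3 or overexpression 1 5, while limma-voom gave 13. Fallen mesothelial genes numbered 5 without control 2, overexpression 1 or overexpression 2, and 10 without control 1 or with limma-voom.

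Neutrophil markers moved with the inflammatory genes. Of 8 tested members 6 rose, among them Lcn2 and Mmp9 (18.1 ± 1.66 to 126 ± 14.6 CPM), and Cxcr1 fell (6 and 1 adjusted over the list alone, camera adjusted p = 2.1e-04, adjusted p = 0.33 with an estimated correlation). B cell markers had no member past the threshold among 16 tested (0 adjusted over the list alone), with the list shifted downward (camera adjusted p = 0.0080, adjusted p = 0.75 with an estimated correlation), a call lost without control 1 or overexpression 3 (adjusted p = 0.12 and 0.27). Of these markers 2 fell with DESeq2 and 4 without a filter on low counts. Of 15 T and NK cell markers Il7r fell (1 adjusted over the list alone, camera adjusted p = 0.90). Leaving out control 1 and overexpression 3, chosen after seeing the data, gave 8 risen and 1 fallen T and NK cell markers. For overexpression 3 alone the median log2 difference of that list was -1.71, against -0.25 with all libraries. Neither Cxcr1 nor Il7r passed without control 2 (adjusted p = 0.11 and 0.080), control 3 (0.14 and 0.055), overexpression 1 (0.11 and 0.051) or overexpression 2 (0.12 and 0.10). Of 9 dendritic cell markers Clec9a and Ccr7 rose and Fscn1 fell (2 and 1 adjusted over the list alone, camera adjusted p = 0.98), the Ccr7 call being lost without control 2 (adjusted p = 0.052). None of 6 mast cell and basophil and none of 6 endothelial markers passed (0 and 0 adjusted over the list alone, camera adjusted p = 0.29 and 0.93). With limma-voom 2 mast cell markers fell, 2 endothelial markers rose and 1 fell, and 2 T and NK cell markers rose. Of 2 tested eosinophil markers Siglecf fell (1 adjusted over the list alone), and no erythroid marker had enough counts.

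Transcripts of the mitochondrial genome took 2.19, 3.76 and 4.21% of counts in control libraries 1, 2 and 3 and 0.856, 2.02 and 2.23% in the overexpression libraries. Of 14 tested mitochondrially encoded genes 5 fell (10 fell and 1 rose adjusted over the list alone, camera adjusted p = 7.0e-04, adjusted p = 0.67 with an estimated correlation), and none did when control 2, control 3, overexpression 1 or overexpression 2 was left out. Without control 1 the number was 8, without overexpression 3 it was 10, and DESeq2 and limma-voom gave 10 and 11. Of 55 ribosomal protein genes none passed in edgeR (0 adjusted over the list alone, 4 without overexpression 3, 3 with limma-voom, 1 with DESeq2), with the list shifted upward (camera adjusted p = 2.6e-05, adjusted p = 0.87 with an estimated correlation). Of 22 immediate early genes 3 rose and 3 fell (4 and 4 adjusted over the list alone, camera adjusted p = 0.74, with none fallen without control 1, control 2 or overexpression 2), and limma-voom gave 7 risen and 4 fallen. Of 6 replication-dependent histone genes 1 fell (1 adjusted over the list alone, camera adjusted p = 0.54), and none did without any 1 library except overexpression 3.

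Among the remaining lists, extracellular matrix remodelling had 7 risen and 1 fallen of 23 genes (9 and 1 adjusted over the list alone, camera adjusted p = 9.9e-05, adjusted p = 0.34 with an estimated correlation), with Timp1, a metalloproteinase inhibitor, up from 12.7 ± 2.56 to 219 ± 76.8 CPM, and limma-voom gave 14 risen and 3 fallen. None fell when any 1 library except overexpression 3 was left out. Oxidative stress had 6 risen of 23 (8 adjusted over the list alone, camera adjusted p = 0.0031, adjusted p = 0.50 with an estimated correlation), among them the cystine transporter gene Slc7a11, from 39.1 ± 3.01 to 222 ± 40.0 CPM, and 11 rose without overexpression 3 and 12 with limma-voom. Oxidative phosphorylation had 1 risen and 1 fallen of 48 (0 and 0 adjusted over the list alone, camera adjusted p = 0.0093, adjusted p = 0.87 with an estimated correlation), a call lost without control 1 or overexpression 1 (adjusted p = 0.21 and 0.36). Of its members 11 rose and 2 fell without overexpression 3, and 9 and 3 with limma-voom. None rose without any other 1 library or with upper-quartile scaling or library size alone, and none fell without control 2, control 3 or overexpression 2. Complement and coagulation had 8 risen and 10 fallen of 30 (8 and 11 adjusted over the list alone, camera adjusted p = 0.71), with C3 up from 342 ± 98.2 to 1513 ± 205 CPM and the complement inhibitor gene Cd55 down from 51.9 ± 27.5 to 2.04 ± 0.620 CPM. Without overexpression 2 the complement list had 6 risen and 3 fallen, and without control 2 6 and 4, more risen than fallen. Lysosome and phagocytosis had 3 risen and 2 fallen of 40 (3 and 2 adjusted over the list alone, camera adjusted p = 0.54), with Lipa, lysosomal acid lipase, down from 1136 ± 40.1 to 303 ± 108 CPM. None of them rose without control 2, control 3 or overexpression 2, and 6 did without overexpression 3. Library size as the only scaling gave 1 risen and 3 fallen, upper-quartile scaling 1 and 2, and limma-voom 10 and 7.

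Apoptosis and p53 genes had 4 risen and 1 fallen of 28 (5 and 2 adjusted over the list alone, camera adjusted p = 0.56), with Cdkn1a up from 69.4 ± 5.91 to 302 ± 138 CPM. Unfolded protein and amino acid stress genes had 3 risen of 29 (3 adjusted over the list alone, camera adjusted p = 0.90), and heat shock genes 2 fallen of 14 (2 adjusted over the list alone, camera adjusted p = 0.56). Without control 2 or overexpression 2 these 3 lists had 2 risen, 1 risen and 1 fallen, and with library size as the only scaling the p53 list had 3 risen and 3 fallen. In the unfolded protein list 1 rose with library size alone, and 7 rose and 4 fell with limma-voom. The p53 list had 9 risen and 3 fallen with limma-voom and the heat shock list 1 and 4. Medians, means and tests differed in sign for the Toll-like receptor, large peritoneal macrophage, cholesterol, p53, unfolded protein, immediate early, dendritic, endothelial and T and NK cell lists, none of which was called. Of the 38 lists tested, 13 were shifted upward and 6 downward by camera, none with an estimated correlation, and 13 moved in 1 direction by limma's fry test.

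**Figure D3:**
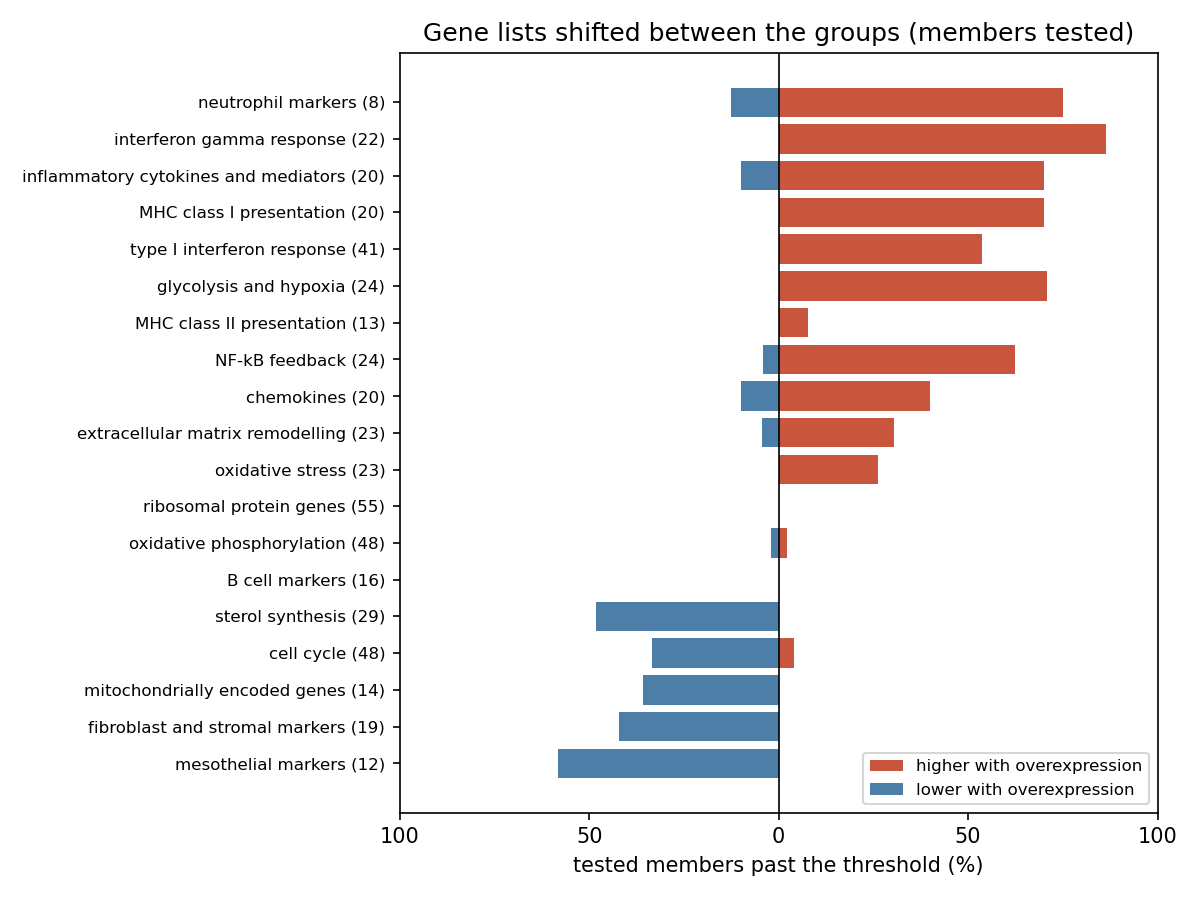
Share of tested members past the threshold, in percent, for the 19 gene lists shifted in the camera test with a preset correlation, higher members to the right in red and lower members to the left in blue; the number of tested members stands in parentheses. The interferon gamma list has 19 of 22 members higher and the mesothelial list 7 of 12 lower.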

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

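Every alternative kept the sign of all 1731 called genes it tested. Each refit used the same libraries or some of them, so this was likely from the start and is weak support. Of 105 named genes past the threshold, 72 lost their call in no refit fixed before the data were examined (95 over the refits that leave out no library). Genes that a refit did not test count as kept there, and the stricter thresholds were not part of this count. Of all 1731 calls, 708 were shared by the fit without overexpression 2 and 725 by the fit without control 2. Alternatives that left out 2 libraries were chosen after seeing the data. Counts of higher and lower genes (928 and 803) were 2442 and 2661 with limma-voom, 1363 and 1207 with DESeq2, 1457 and 1460 without a filter on low counts, 421 and 250 at an adjusted p under 0.01, 454 to 1657 and 250 to 1800 with 1 library left out, 1922 and 2022 without control 1 and overexpression 3, and 261 and 87 for overexpression 3 alone, whose spread was taken from the controls; fewer libraries are part of these last changes, and the cause of the others was not tested. The Rfx1 log2 difference (0.27) ran from -0.10 to 1.37 with 1 library left out and was -0.25 for overexpression 3 alone. It was 1.59 without control 1 and overexpression 3 (edgeR adjusted p = 3.4e-05, against 0.024 or more over the other alternatives). Those are the control with the most Rfx1 and the overexpression library with the least, so leaving them out widens the difference by construction. The cause of these shifts was not tested beyond the library levels of Rfx1. For overexpression 3 alone H2-Ab1 was -0.42, Cd74 -1.49 and Ccl2 -0.86, the signed -log10 p was -0.15 for the MHC class II list and -0.14 for oxidative phosphorylation, and 7 lists were higher and 7 lower. Ccl2 ran from -0.010 (without control 1) to 1.02 with 1 library left out. No list was called with an estimated correlation (0 higher and 0 lower, with 4 at an unadjusted p under 0.05), and fry called 10 higher and 3 lower. Whether replicate numbers pair the libraries was not settled, and the labels do not say. Correlations of same-numbered deviations were 0.094, 0.0053 and 0.33, against -0.232 to 0.19 for the other pairs across groups. The replicate block gave 957 higher and 945 lower genes, an Rfx1 log2 difference of 0.62, and 13 and 6 lists. With it H2-Ab1, Cd74 and Arg1 passed (edgeR adjusted p = 0.0055, 0.023 and 0.020). Cd180, Cycs, E2f1 and Hspb1 no longer did (adjusted p = 0.060, 0.059, 0.074 and 0.063). Depth was not tested apart from the simulated counts, and with at least 5 CPM in 3 libraries 717 genes were higher and 538 lower.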

Other observations

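All tests of explanations in this part were chosen after the values they bear on had been seen, except the counts over other splits of the libraries. With 3 libraries against 3 there are 10 splits, too few for a share under 0.05. The labelled split gave 1731 genes, 928 higher and 803 lower, and the highest of the other splits 0 in the same edgeR model, so 1 split gave as many for each of these counts. At an unadjusted p under 0.05 the labelled split gave 3819 genes and the highest of the others 1266. For gene lists the labelled split gave 19 and the highest other split 21, so 2 of the splits gave as many. That other split sets control 1, overexpression 1 and overexpression 2 against the rest.

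Wdfy1, chosen after its values were seen, parted the libraries in that way rather than by label. It had 51.9, 9.21 and 11.1 CPM in control libraries 1, 2 and 3 and 53.3, 55.9 and 11.8 CPM in the overexpression libraries. Rfx1 itself parted the libraries in the same way. It had 57.6, 40.8 and 36.4 CPM in control 1, overexpression 1 and overexpression 2, against 11.0, 14.8 and 23.2 in control 2, control 3 and overexpression 3. H2-Ab1 had 599, 2090 and 1533 CPM in the former libraries and 160, 63.2 and 203 in the latter. Il22, a cytokine gene also chosen after its values were seen, had 0 counts in every control and 1.98, 4.14 and 4.49 CPM with overexpression (edgeR adjusted p = 0.0019).

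Inflammatory and interferon genes were higher in the overexpression libraries, with 78 risen members over 5 lists. Whether neutrophils were mixed into these cultures was not decided by the neutrophil list. There 9 of 17 members had a mean under 1 CPM, which goes against neutrophils, but 6 of the 8 tested members rose (median log2 change of the tested members 3.68). S100a9, chosen after its values were seen, reached at most 0.793 CPM in any library, while S100a8 reached up to 335 CPM. Scaling is argued against as the whole cause, since 91.0% of the risen members kept their call under the scaling that kept fewest. Whether the level of Rfx1 mRNA goes with these genes cannot be told apart from other differences between the groups. Control 1, with the most Rfx1, lay 28.4% of the way from the other controls to the overexpression mean. Overexpression 3, with the least Rfx1 of its group, lay 74.2% of the way from the control mean to the other overexpression libraries. The order of Rfx1 mRNA was thus not the order of these genes, but 1 library of each group decides nothing. An untested stimulus that differed between the cultures stays open, as does the overexpression itself.

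Mesothelial and stromal genes were lower in the overexpression libraries. Fewer mesothelial cells may account for the mesothelial part, since 11 of 12 tested markers had a log2 change under -1; a lower expression within the same cells would look alike in these data. Controls also differed among themselves, with 11 of 12 markers higher in control 2 than in control 1. Among the fallen members of other lists, Gata6, Edn1, Csf1, Cxcl13, Cxcl5, Cd55 and Fscn1 were likewise lowest in control 1 of the controls. The same held for fallen cell cycle, sterol and mitochondrial genes such as Ccnb2, Cyp51 and mt-Nd4. A low level in control 1 is thus not particular to mesothelial genes. Cd5l and Mrc1 were highest in control 1. Whether Gata6 and the genes named with it fell with the mesothelial and stromal genes was not tested. Whether fewer fibroblasts account for the stromal part cannot be told apart from other causes, since 9 of 19 tested markers had a log2 change above -1 but only 3 of them by more than 2 standard errors. An effect of Rfx1 overexpression on these genes was not tested separately.

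Lyz2, the macrophage lysozyme gene (chromosome 10, positions 117277331 to 117282321 of mm10) and chosen after its values were seen, had 15672, 38702 and 28352 CPM in the controls and 44.7, 40.8 and 29281 CPM in overexpression libraries 1, 2 and 3. It ranked 1 of 13454 tested genes by its range among the overexpression libraries, 9.48 log2 units against 5.89 for the next. Reads assigned to the neighbouring paralog Lyz1 are argued against by its highest level, 332 CPM, and loss of the surrounding chromosome segment by 9 genes of at least 5 CPM within 0.5 Mb, whose largest excess in overexpression 3 was 0.63 log2 units. An allele that disrupts Lyz2, such as an inserted recombinase gene, is a candidate explanation that gene counts cannot decide; the labels name no such genotype, and cells of another origin stay open too.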
